A study of Drosophila melanogaster with 4 samples.

How the data were processed

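The samples were pools of whole Drosophila melanogaster females, either virgin or frozen 1 to 3 h after mating with DTA-E, spermless or wild-type males, with 1 value column for each of the 4 groups. Per the labels, each treatment had 2 RNA extractions from pools of 50 flies and 4 chips in all, 20 µg of labelled cRNA per hybridisation and 16 h of hybridisation at 45 °C. How the 4 chips were combined into 1 column is not given in the sources used here, nor are the image analysis and scaling software. The deposited values, made by the authors, are on a log scale and were read as log2; the base is not stated. Each column had a mean near 0, so a scaling of each array can be seen in the values, whereas genes were not centred. Because values were already logged, the linear offset planned before the data were examined did not apply, and the plan for log values was used. Direction is fixed by the column names: each difference is the group named before "against" or "minus" less the other.

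Probe sets were named through the platform annotation with symbols updated by Entrez identifier from a RefSeq gene table. Of the probe sets, 12443 had 1 gene symbol, 326 had several and 1196 had none. Identifiers of 12393 probe sets were found in the RefSeq table and 50 were not, which kept the older symbol. The 44 control probe sets were left out of all comparisons and used for quality values. Probe sets with several symbols or none were left out of the gene comparisons. Genome positions were not used here. A probe set was kept when the highest of its 4 columns was at or above the median of all values (-0.18). Each column was centred on its median over kept probe sets, which moved columns by at most 0.05 against the virgin column, and probe sets of a gene were averaged, which concerned 294 genes.

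The comparisons, lists, naming rule and thresholds were fixed before the data were examined, except where the text says otherwise. The 4 comparisons were wild-type against virgin (mating), DTA-E against virgin (mating without sperm or main-cell Acps), spermless against DTA-E (Acps) and wild-type against spermless (sperm). With 1 column per group there is no test, p-value or standard error, and counts are of genes past a 2-fold difference. The rule let the text name, without requiring each, the 12 highest and 12 lowest genes of each comparison with a symbol other than an annotation number, the 4 highest and 4 lowest of any name, and of each list the 4 measured members with the largest difference. Def and Drs, and other genes named in the closing section, were chosen after their values were seen.

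There were 25 gene lists: antimicrobial peptides, immune recognition and signalling, digestive serine proteases, spermathecal proteases, yolk proteins, eggshell, ovarian germline, DNA replication, male accessory gland proteins, testis and spermatid genes, juvenile hormone and ecdysone, odorant binding proteins, cytochrome P450, glutathione transferases, UDP-glycosyltransferases, circadian clock, heat shock and chaperones, muscle, ribosomal proteins, carbohydrate digestion, neuropeptides and insulin-like peptides, phototransduction, lipid metabolism, cuticle proteins, and immediate early and stress kinase targets. A list needed at least 4 measured genes, which left out the accessory gland list and gave 24. Each list median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and was called outside the random range below percentile 2.5 or above 97.5. Such percentiles describe these columns only, since genes of a list can vary together. The procedure was tested on simulated data for the mating comparison with 6275 genes. All 50 genes set 1.50 higher and all 50 set -1.50 were counted past 2-fold, and so were 0 of 6075 unchanged genes. Of the 50 set 0.80 higher and the 50 set -0.80, 0 were counted. The simulated noise was independent between probe sets and held no variation between pools of flies. These counts therefore check the calculation and do not measure false counts in the deposited columns. Of 100 unshifted lists, 7 lay outside the range.

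Alternatives were columns as deposited, quantile normalization, no filter, a stricter filter at the 75th percentile of all values, the brightest probe set of a gene, removal of an intensity trend by lowess (fraction 0.3, 3 iterations), thresholds of 1.5-fold and 3-fold, and random lists without matching. Other comparisons were added after seeing the data. Some left out the spermless or the DTA-E column, or the muscle and cuticle lists together with the cuticle gene Acp1. Others were of the P450, hormone and ribosomal lists without members of another kind that their names had brought in. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, with random seed 1.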

Results

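Whole female Drosophila melanogaster were compared on an Affymetrix Drosophila GeneChip after no mating or after mating with males that differed in what they pass to the female. There were 4 groups. Virgin females were the unmated state. The DTA-E males carry a toxin transgene that leaves them without sperm and with 96% of the main secretory cells of the accessory gland missing, so their mates received neither sperm nor main-cell accessory gland proteins (Acps). Spermless males, which the labels call sons of tudor, pass Acps without sperm, and wild-type males pass both. The label of the group mated to wild-type males names the females as Canton S. Females were 3 to 4 days old, were reared at 25 °C and were frozen 1 to 3 h after mating in pools of 50. The labels describe 2 RNA extractions and 4 chips per treatment. The value table holds 1 column per treatment and 14009 probe sets, so no replicate values were available. No test could be made, and each difference below is the difference between 2 columns.

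The deposited values are on a log scale whose base is not stated. They ran from -1.98 to 5.67, with column medians of -0.18 in virgin females, -0.19 after DTA-E males, -0.18 after spermless males and -0.17 after wild-type males. The text reads them as log2, where a difference of 1 is 2-fold; on a natural log scale it would be 2.72-fold. The columns were close to each other, with Pearson correlations across probe sets of 0.993 to 0.996. After filtering, 6534 probe sets for 6201 genes were compared, and in each of the 4 comparisons 98.8% to 99.4% of the genes differed by less than 1.5-fold. For genes with several probe sets, the SD of the difference between probe sets was 0.08 to 0.09. The number of arrays limits the precision, and that SD does not cover differences between pools of flies. The mean of 9 hybridization control probe sets differed by 0.16 in wild-type against virgin, -0.08 in DTA-E against virgin, 0.17 in spermless against DTA-E, 0.07 in wild-type against spermless and 0.23 in wild-type against DTA-E, more than many of the list medians below. The mean of the 23 other foreign control probe sets, as deposited, was -1.26 in virgin females, -1.26 after DTA-E males, -1.19 after spermless males and -1.22 after wild-type males. The 3' minus 5' difference of the actin control probe sets, a sign of RNA integrity, was 1.95 in virgin females, 2.26 after DTA-E males, 2.02 after spermless males and 1.97 after wild-type males.

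The whole difference made by mating was read from females mated to wild-type males against virgin females. Genes for carbohydrate digestion were lower in the mated column. The maltase genes Mal-A1 (-2.18), Mal-A6 (-1.64), Mal-A7 (-1.41) and Mal-A8 (-1.21), the alpha-glucosidase gene tobi (-1.73) and the amylase gene Amy-d (-1.11) were all more than 2-fold lower. Mal-A1 had a value of 2.96 in virgin females and 0.77 after wild-type males, which is 4.54-fold on the log2 scale. All 12 measured members of the carbohydrate digestion list were lower, 7 of them past 1.5-fold, and the list median of -0.90 lay below all 10000 random lists matched on mean expression. The median was -1.39 under the stricter filter. Among digestive serine proteases, betaTry and alphaTry, which encode trypsins, were lower by -1.23 each and Jon74E by -1.29. The list of 24 trypsin and Jonah genes was mixed, with 16 lower and 8 higher, and its median was -0.21, below all random lists. Jon99Fi, of the same family, was higher by 0.63. The gut aspartic protease gene Bace was lower by -1.52. CG4363 (-1.94) and CG7953 (-1.46) were also among the lowest genes, although CG7953 was at -0.77 without the filter on low probe sets.

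Of the muscle list, 3 genes were more than 2-fold lower. Act88F, the flight muscle actin, differed by -1.65, the flight muscle troponin C gene TpnC4 by -1.38 and the thick filament gene fln by -1.33. These stood apart from most of the muscle list, whose 22 members, these 3 included, had a median of -0.08. Over that list 15 members were lower and 7 higher, at percentile 0.45 of random lists, and the median was -0.04 after quantile normalization. The cytochrome P450 list, of genes that often act in detoxification, had a median of -0.07 over 29 members, but it had taken the cyclophilin genes Cyp1 and Cyp40 by their names. Without these, as in the P450 counts below, a choice made after seeing the data, 21 of 27 genes were lower with a median of -0.08. Cyp6d5 (-0.99), Cyp6g1 (-0.78), Cyp28d1 (-0.74) and Cyp9f2 (-0.72) led them, and under the stricter filter the median of the full list was -0.35. Of 12 odorant binding protein genes 11 were lower, with a median of -0.15 at percentile 0.01, and Obp99c differed by -0.55. That median was -0.02 without the filter.

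Fewer genes were higher after mating with wild-type males. The largest differences belonged to CG3348 (1.27), Send2 (1.23), a serine protease gene of the spermathecal secretory cells, and fit (1.11), a female-biased gene of the fat body. Send1 was higher by 0.54, whereas CG9897 (-0.09) and CG32277 (-0.04), the other members of the spermathecal list, were close to 0. That list of 4 had a median of 0.25, above all random lists. Antimicrobial peptide genes were higher in 5 of 6 cases. Mtk (0.96), DptB (0.79) and BomS2 (0.59) were past 1.5-fold and Drsl5 (-0.26) was lower. The median of 0.45 lay above all random lists. It was 0.27 without the filter, when weakly detected members of the list entered. Eggshell genes were higher in 11 of 14 cases with a median of 0.17, above all random lists, led by the chorion genes Cp15 (0.74), Cp19 (0.56) and Cp18 (0.56). The chorion gene Cp7Fc went the other way at -0.31. Cuticle protein genes were higher in 28 of 30 cases by small amounts, with a median of 0.10, or 0.04 without the filter. The foreign control probe sets were also higher in that column than in the virgin column. Cipc, the homologue of a CLOCK-interacting repressor, was higher by 0.93, and the mucin gene Muc12Ea by 0.61.

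In all, 3 genes were at least 2-fold higher and 26 at least 2-fold lower after mating with wild-type males. These counts describe 1 pair of columns.

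**Figure D1:**
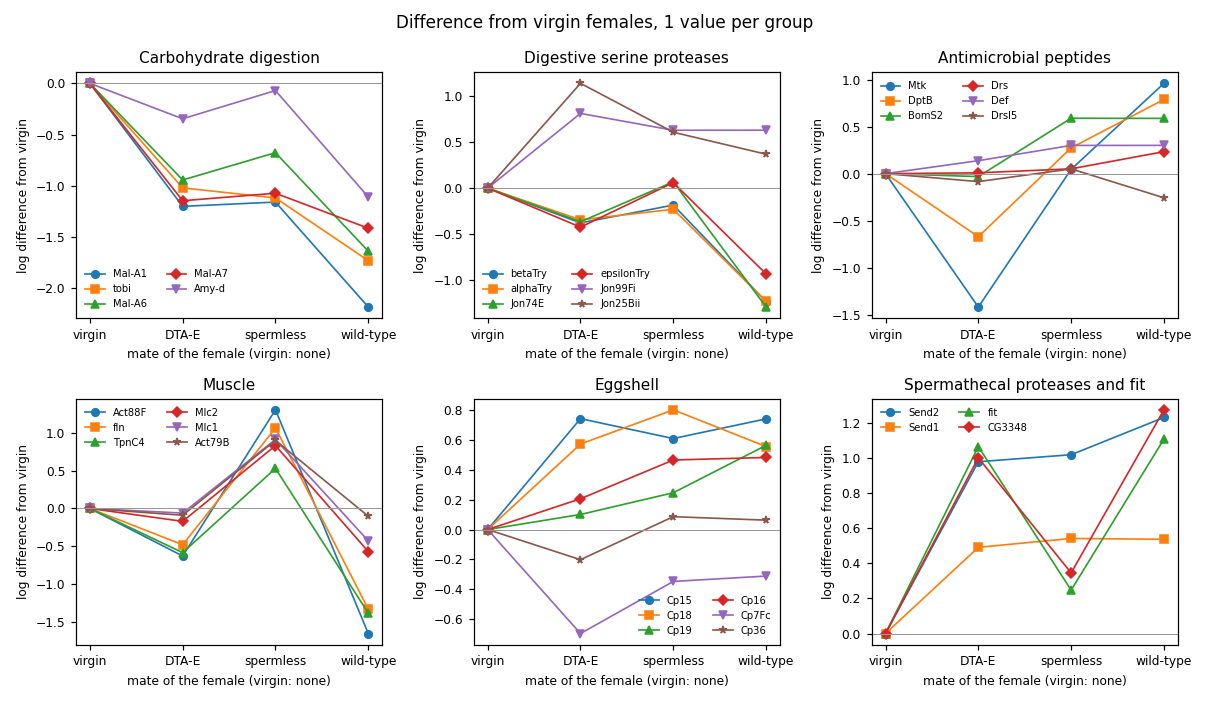
Log difference from virgin females (vertical axes, log units as deposited, 1 value per group, no error bars because there is 1 column per group) against the mate of the female for named genes of 6 groups. Lines join the values of a gene. Mal-A1 lies at -1.20 after DTA-E males and -2.18 after wild-type males, Mtk is lowest after DTA-E males at -1.42, and Act88F is highest after spermless males at 1.30.

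Mating without sperm and without main-cell Acps was read from females mated to DTA-E males against virgin females. The carbohydrate digestion genes were already lower in this comparison. Mal-A1 differed by -1.20, Mal-A7 by -1.14, tobi by -1.02, Mal-A6 by -0.94, Mal-A8 by -0.91 and Mal-A4 by -0.63. The list median was -0.50, below all random lists, with 11 of 12 members lower. Under the stricter filter the median was -0.96. The spermathecal protease genes Send2 (0.98) and Send1 (0.49) were higher, and their list of 4 had a median of 0.23. fit was higher by 1.06, and CG3348 was 0.13 in virgin females and 1.13 after DTA-E males. The CG3348 difference was just short of 2-fold, at 0.98, after quantile normalization.

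Digestive proteases did not move as a block after DTA-E males. Jon25Bii (1.13), Jon25Bi (0.82) and Jon99Fi (0.81) were higher, while betaTry (-0.38), Jon74E (-0.36) and alphaTry (-0.34) were lower. Over the 24 members 15 were lower and 9 higher, and the median was -0.08, below all random lists. Lsd-1, which encodes a perilipin of lipid droplets, was higher by 0.82. The metallothionein genes MtnB (0.66) and MtnC (0.55) and the small heat shock protein gene l(2)efl (0.55) were higher too. The chorion genes Cp15 (0.74) and Cp18 (0.57) were higher and Cp7Fc was lower by -0.70. The eggshell median was 0.11 at percentile 99.9, with 10 of 14 members higher. The juvenile hormone and ecdysone list had 8 of 9 members higher by small amounts, with a median of 0.10, or 0.01 without the filter. It includes Phm, a peptide amidating enzyme gene taken by its name, and without it, also chosen after seeing the data, 7 of 8 were higher with a median of 0.11. ftz-f1, a nuclear receptor gene, differed by 0.12 and sad, an ecdysone synthesis gene, by 0.10. Jheh2, the only measured member named for juvenile hormone, was the member that was lower, at -0.055.

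Several immune genes were lower in the DTA-E column, although neither immune list lay outside random lists. Mtk, encoding the antimicrobial peptide metchnikowin, was 1.31 in virgin females and -0.11 after DTA-E males, a difference of -1.42. DptB, a diptericin gene, differed by -0.67, BomS5, a bomanin gene, by -0.55 and PGRP-SB1, a peptidoglycan recognition protein gene, by -0.46. Tsf1, encoding the iron carrier transferrin, differed by -0.72. The antimicrobial list as a whole had 4 of 6 members lower and a median of -0.06, inside the range of random lists at percentile 3.55. Def was higher by 0.14 and Drs by 0.01. The immune recognition and signalling list had a median of -0.01 at percentile 23.7. Of 27 P450 genes 24 were lower, led by Cyp6d5 at -0.68, with a median of -0.08. The median of the full list was -0.07, or -0.02 without the filter and -0.27 under the stricter filter. Act88F differed by -0.63, and the muscle list had a median of -0.05 with 15 of 22 members lower. The DTA-E column also had the highest 3' minus 5' differences for eIF-4a (1.97 against 1.70 in virgin females) and GAPDH (1.97 against 1.79), as it did for actin. In all, 3 genes were at least 2-fold higher and 8 at least 2-fold lower.

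The question of what Acps add in the absence of sperm was read from females mated to spermless males against females mated to DTA-E males. Muscle genes were higher after spermless males. Act88F differed by 1.93, fln by 1.54, TpnC4 by 1.11, the actin gene Act79B by 0.99 and the myosin light chain gene Mlc1 by 0.97. Mlc2, another myosin light chain gene, was 3.11 after DTA-E males and 4.11 after spermless males. In all, 21 of the 22 muscle genes were higher, 8 of them past 1.5-fold, with a median of 0.40 above all random lists. Mpcp1, a mitochondrial phosphate carrier gene, was higher by 0.96. The adult cuticle genes Acp65Aa (1.07) and Acp1 (1.05) and the gene Cpr49Ae (0.81) were higher. In all, 29 of 30 cuticle genes were higher with a median of 0.07, or 0.02 in the columns as deposited. The foreign control probe sets were higher after spermless males too, so a background difference was not separated from that small median. CG7214 went from -0.18 after DTA-E males to 1.73 after spermless males, a difference of 1.91. In 21 of the 22 muscle genes, and in Acp65Aa, Acp1, Cpr49Ae and CG7214, the spermless column was higher than all 3 others. Act88F was 2.58 there, against 1.27 in virgin females, 0.64 after DTA-E males and -0.38 after wild-type males. Of the 30 cuticle genes, however, 18 were higher after wild-type than after spermless males.

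Antimicrobial peptide genes were also higher after spermless males than after DTA-E males. Mtk differed by 1.47, BomS5 by 1.09, DptB by 0.95, BomS2 by 0.62 and PGRP-SB1 by 0.53. All 6 members of the antimicrobial list were higher, 3 of them past 1.5-fold, and the median of 0.39 lay above all random lists. It was 0.11 without the filter. Against virgin females, however, Mtk was higher by 0.05 and DptB by 0.27 in the spermless column, while BomS2 was higher by 0.59 and BomS5 by 0.55. The 3' minus 5' difference of actin was larger in the DTA-E column of this comparison. Digestive genes were higher by less. The carbohydrate digestion list had 11 of 12 members higher and a median of 0.09 at percentile 99.3, with Mal-A1 at 0.04 and tobi at -0.10, and that median was 0.03 without the filter. The digestive protease list had 18 of 24 members higher and a median of 0.13 above all random lists, or 0.07 without the filter.

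Several genes were lower after spermless males than after DTA-E males, none of them past 2-fold. Obp99a, an odorant binding protein gene, differed by -0.90, CG34166 by -0.85, fit by -0.82 and CG3348 by -0.66. mtrm, which encodes an inhibitor of Polo kinase in oocyte meiosis, differed by -0.54, Jon25Bii by -0.53 and MtnC by -0.51. The lipid metabolism list had a median of -0.01 with 7 members on each side. Among them were apolpp, the lipophorin precursor gene (-0.44), the storage protein gene Lsp2 (-0.37) and Lip4 (0.18). The fatty acid synthase gene FASN1, which was not among the measured members of that list, differed by -0.38. Heat shock and chaperone genes were lower in 8 of 10 cases with a median of -0.13 at percentile 0.37, led by Hsp110 (-0.22) and Hsp27 (-0.20), whereas stv was higher by 0.20. That median was -0.06 without the filter and -0.08 with the intensity trend removed. P450 genes were higher in 20 of 27 cases with a median of 0.06 at percentile 99.4, and the median of the full list was 0.05, or 0.01 in the columns as deposited.

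In all, 10 genes were at least 2-fold higher and 0 at least 2-fold lower after spermless males than after DTA-E males. Without the muscle and cuticle lists and the cuticle gene Acp1, 4 genes were higher. With the wild-type column in place of the spermless column, which makes it wild-type against DTA-E, there were 2 higher and 3 lower. Both alternatives were chosen after seeing the data. Mlc2, at the edge of the threshold, was at 0.95 in the columns as deposited.

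What sperm add was read from females mated to wild-type males against females mated to spermless males. Muscle genes were lower in the wild-type column, the mirror of the previous comparison through the shared spermless column. Act88F differed by -2.96, fln by -2.40, TpnC4 by -1.91, Mlc2 by -1.40 and Mlc1 by -1.34. All 22 muscle genes were lower, 9 past 1.5-fold, and the median was -0.46, below all random lists. Mpcp1 (-1.49) and ND-B8 (-1.43), a gene of mitochondrial complex I, were lower with them. CG7214 differed by -2.29, Acp1 by -1.24 and Acp65Aa by -1.16. The cuticle list as a whole had a median of 0.02, with 18 members higher and 12 lower.

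Digestive genes were lower in the same comparison. Jon74E differed by -1.36, betaTry by -1.05, Amy-d by -1.04, Mal-A1 by -1.02, Bace by -0.97 and Mal-A6 by -0.96, and alphaTry was 3.65 after spermless males and 2.65 after wild-type males. All 12 carbohydrate digestion genes were lower with a median of -0.29, and 21 of 24 digestive proteases were lower with a median of -0.28, both below all random lists. Under the stricter filter these medians were -0.61 and -0.47. Amy-d and betaTry were at -0.91 and -0.94 after quantile normalization, and Mal-A1 was just under 2-fold lower in the columns as deposited. P450 genes were lower in 20 of 27 cases with a median of -0.08, the full list being at -0.07, or -0.04 in the columns as deposited. Odorant binding protein genes were lower in 9 of 12 cases with a median of -0.11, although Obp99a was higher by 0.71. The odorant binding median was -0.04 without the filter and -0.26 under the stricter filter. The phototransduction list had a median of -0.09, with Arr1, an arrestin gene of photoreceptors, at -0.31.

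The genes that were higher with sperm differed by less. CG34166 (0.98), CG3348 (0.93), Mtk (0.92), Uhg1, a host gene of small nucleolar RNAs (0.88), and fit (0.86) led, followed by DptB (0.51) and mtrm (0.47). In wild-type against DTA-E, Mtk (2.38), DptB (1.46) and Uhg1 (0.63) were higher too. CG3348 (0.27), CG34166 (0.13), fit (0.04) and mtrm (-0.06) differed by less there. The sperm values of these last genes largely mirror lower values after spermless than after DTA-E males. The antimicrobial list had 4 of 6 members higher and a median of 0.09 at percentile 97.8, or 0.01 without the filter, with BomS2 at 0.00 and Drsl5 at -0.31. Germline genes of the ovary were higher in 20 of 24 cases with a median of 0.10, above 99.99% of random lists. osk, the organiser of germ plasm, was higher by 0.23, pum, a translational repressor gene, by 0.23 and swa by 0.17. This mirrors a low spermless column, since the list was at -0.07 in spermless against virgin females and at 0.01 in wild-type against virgin females. Eggshell genes were higher in 11 of 14 cases with a median of 0.11, and heat shock and chaperone genes in 8 of 10 cases with a median of 0.14. The latter was 0.04 without the filter and 0.23 after quantile normalization, and it too mirrors the spermless column, since the list was at 0.01 in wild-type against DTA-E. DnaJ-1 was higher by 0.28 and Hsc70-5 by 0.24. The juvenile hormone and ecdysone list had a median of 0.07, or 0.08 without Phm, and the full list was of opposite sign at -0.004 without the filter. Its member Jheh2 was lower, at -0.127. mam, a Notch coactivator gene, was higher by 0.35 and dpr3, of an immunoglobulin family of neurons, by 0.41. Each has 1 probe set, and the 2 had nearly the same values in wild-type against virgin (0.279 and 0.281) and DTA-E against virgin (-0.127 and -0.128). In wild-type against DTA-E they were at 0.405 and 0.409. Their values need not be independent, and whether each probe set measures only its named gene was not tested.

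In all, 0 genes were at least 2-fold higher and 22 at least 2-fold lower with sperm. Quantile normalization gave 2 higher and 17 lower. Without the muscle and cuticle lists and the cuticle gene Acp1, 14 were lower. The same comparison of wild-type against DTA-E had 2 higher and 3 lower. Both alternatives were chosen after seeing the data.

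**Figure D2:**
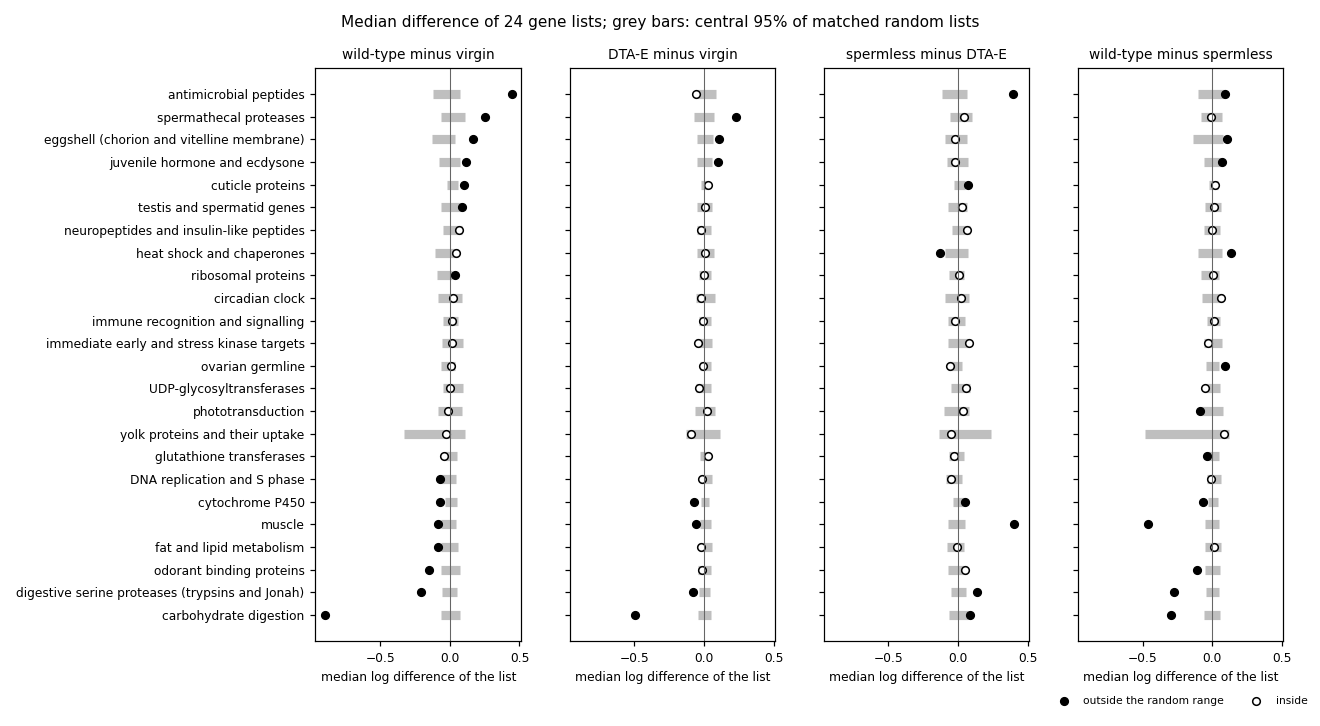
Median log difference (horizontal axes, log units as deposited) of 24 gene lists in the 4 comparisons, with grey bars for the central 95% of 10000 random lists matched on mean expression and filled points for lists outside that range. The carbohydrate digestion list lies at -0.90 in wild-type minus virgin, and the muscle list at 0.40 in spermless minus DTA-E and -0.46 in wild-type minus spermless.

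The mating difference is the sum of its 3 steps, and its genes divided between them. Of the 26 genes at least 2-fold lower after wild-type males, 10 had their largest part at the step from virgin to DTA-E, 16 at the step from spermless to wild-type and 0 at the step from DTA-E to spermless. The genes were selected on the wild-type and virgin columns, which favours the outer steps, since the Acp step uses neither column. For Act88F, fln and TpnC4, which were high in the spermless column, the sperm step (-2.96, -2.40 and -1.91) was larger than the total. Mal-A7 and tobi belonged to the former kind, at -1.14 and -1.02 of totals of -1.41 and -1.73. Jon74E, betaTry, alphaTry, Bace and Amy-d had their larger part with sperm. All 3 genes at least 2-fold higher, fit, Send2 and CG3348, had their largest part at the step to DTA-E. fit and CG3348 were lower at the Acp step and higher again at the sperm step. Across genes, which are not independent replicates, the steps that share no column (DTA-E minus virgin, and wild-type minus spermless) correlated at Pearson 0.287 and Spearman 0.163. Spermless minus DTA-E correlated with wild-type minus virgin at Pearson -0.153 and Spearman 0.072. Spermless minus virgin correlated with wild-type minus DTA-E at Pearson 0.130 and Spearman 0.238. Neighbouring steps share a column with opposite sign and so correlate negatively by noise alone. Their Pearson values were -0.412 for the steps to DTA-E and to spermless, and -0.674 for the steps to spermless and to wild-type.

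Other fixed lists differed by small amounts or not beyond random lists. The yolk protein genes Yp1 (-0.08), Yp2 (0.14) and Yp3 (0.03) were among the highest values on the array, and with the receptor gene yl (-0.26) their list had a median of -0.03 in mated against virgin females. Immune recognition and signalling genes had medians of -0.02 to 0.02 over the 4 comparisons, and spz, the ligand gene of the Toll receptor, ranged from -0.25 with Acps to 0.26 with sperm. Replication genes were lower after wild-type males than in virgin females in 14 of 16 cases, with a median of -0.07 at percentile 1.59 and Mcm3 at -0.16, and the median was -0.04 under the stricter filter. Lipid metabolism genes had a median of -0.09 at percentile 0.42 and ribosomal protein genes one of 0.04 at percentile 99.7 in that comparison, the latter 0.01 without the filter and inside the range, at percentile 92.1, of random lists drawn without matching. Without 3 genes that the annotation names only as like ribosomal proteins, again chosen after seeing the data, the ribosomal median was 0.03. Glutathione transferase genes had a median of -0.04 in mated against virgin females, with GstT4 at -0.67 and GstE3 at -0.62, and of -0.03 at percentile 1.97 with sperm, which was -0.01 in the columns as deposited. UDP-glycosyltransferases (0.00, with Ugt35C1 at -0.73), clock genes (0.02, with cwo at 0.31), neuropeptide and insulin-like peptide genes (0.06, with Nplp3 at -0.38), and immediate early and stress kinase targets (0.01, with Gadd45 at 0.08) lay inside the range of random lists in all 4 comparisons. Nplp3 was higher by 0.51 with Acps and differed by -0.98 with sperm. Of 33 testis and spermatid genes on the array 8 passed the filter, with a median of 0.09 in mated against virgin females at percentile 98.3, or 0.04 without the filter, and Mst84Db at 0.10. Of 21 symbols taken by the accessory gland list 3 passed. They were Acp1, which is the cuticle gene given above, the serpin gene Spn42Dd (0.11) and peb (-0.03), a transcription factor gene. Over the 24 lists and 4 comparisons, 40 of 96 medians lay outside the central 95% of random lists, against 4.8 expected if genes varied independently.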

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

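For the carbohydrase and antimicrobial genes the tests of scaling and intensity trend were set before their results were seen, and the other tests below only after. Digestive serine proteases and muscle genes drew attention because their list medians against virgin females had opposite signs for different mates, a difference that was not tested because there is 1 column per group. The protease median was 0.100 after spermless males, -0.207 after wild-type males and -0.081 after DTA-E males. The muscle median was 0.440 after spermless males, -0.084 after wild-type males and -0.054 after DTA-E males. Signal also appeared in data outside the gene comparisons: of 811 kept probe sets without a single gene name, 5 were at least 2-fold higher and 1 at least 2-fold lower after wild-type males than in virgin females.

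Muscle genes stood highest in the spermless column, in 21 of the 22 measured members of the list fixed beforehand. Column-wide scaling or an intensity trend is argued against, since the median excess of the list over the other columns was 0.42 and at least 0.40 after either correction. Acps acting whether or not sperm arrive should also raise the list in the wild-type column, which received Acps too. The list median there was -0.05 against DTA-E, with an upper quartile of -0.02, while that of spermless minus DTA-E was 0.40. The comparison does not decide it, because a low wild-type column could hide such a rise. Act88F (-1.65), TpnC4 (-1.38) and fln (-1.33) were lower there than in virgin females, although the list median was -0.08. A difference in age or maturation between the pools cannot be told apart from the male's genotype, because the labels give the same age range for all pools. The cuticle list had a median of 0.02 in wild-type minus spermless, with 18 members higher, by at most 0.12, and 12 lower. That median did not settle the question. Acp65Aa (-1.16), Cpr49Ae (-0.78) and Acp1 (-1.24), a cuticle gene outside the list, were lower, as the muscle genes were. A response to Acps without sperm stays open and untested.

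Digestive carbohydrase genes were lower in each mated column, and scaling or a trend is argued against by the wild-type minus virgin median, which stayed at -0.85 or lower after either correction. For the difference between DTA-E and virgin females, less gut tissue as the whole cause is argued against by the digestive proteases, whose median of -0.08 and lower quartile of -0.20 lay above the upper quartile of the carbohydrases at -0.31, although lysozyme genes (-0.40) and Bace (-0.58) were lower too. A high virgin column cannot be told apart from mating in that difference, because there is 1 virgin column and the spermless and DTA-E columns differed by 0.09. A high virgin column alone is argued against for the whole pattern by wild-type minus spermless, which does not use that column and had a median of -0.29. For that last difference less gut tissue in the wild-type pool may account for the values, since the protease median was -0.28, within the range of the carbohydrases, and lysozyme genes were lower as well.

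Antimicrobial peptide genes were higher after wild-type males than in virgin females in 5 of 6 cases, with a median of 0.45. Scaling or a trend is argued against by the wild-type minus virgin median, which stayed at 0.44 or above after either correction. For Mtk and DptB in the Acp comparison, their mean of spermless minus virgin was 0.16, against 1.21 for spermless minus DTA-E. That part may come from a low DTA-E column, the column with the largest 3' minus 5' differences. Both were picked as the list members lowest in DTA-E against virgin females (-1.42 and -0.67), which favours this outcome. Drsl5 went with them (0.05 against 0.14), but BomS2 (0.59 against 0.62), Def (0.30 against 0.16) and Drs (0.05 against 0.04) did not. No biological explanation was tested.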

How the results depend on the processing

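Each comparison rests on 1 column per group, so no replicate could be left out. No paired analysis was possible because the result comes from no test and each group has 1 column. The planned offsets were not run, since the values were already logged. Depth in the sense of signal over background limits weakly detected genes. The filter removed only probe sets that were weak in all 4 columns. Some kept genes were weak in a column compared, such as Send2 (-1.36) and Cipc (-1.46) in virgin females after centring. Threshold counts moved by construction. At 1.5-fold and 3-fold, mating gave 11 and 0 genes higher and 62 and 5 lower; mating with DTA-E males gave 12 and 0 higher and 24 and 0 lower; the Acp comparison gave 32 and 2 higher, and 4 lower at 1.5-fold; the sperm comparison gave 6 higher at 1.5-fold, and 67 and 5 lower. The mating-lower genes at 1.5-fold divided into 29 with the largest part at the DTA-E step and 32 at the sperm step. Genes higher with sperm numbered 1 in the columns as deposited and 2 after quantile normalization, against 0. In alternatives chosen after seeing the data, leaving out the spermless column turned both the Acp and the sperm comparison into wild-type minus DTA-E, with 2 genes higher and 3 lower, and all 3 of the latter were among the 22 genes lower with sperm. Leaving out the DTA-E column turned the Acp comparison into spermless minus virgin, with 8 genes higher, 6 of them among the 10, and 5 lower. Without the muscle and cuticle lists and the cuticle gene Acp1, the Acp comparison had 4 higher and the sperm comparison 14 lower. The correlation of the Acp and mating comparisons was -0.038 without a filter and -0.253 under the stricter filter, and that of spermless minus virgin with wild-type minus DTA-E was 0.214 and 0.048. The causes of these shifts were not tested beyond the construction of each alternative. The juvenile hormone and ecdysone median with sperm reversed to -0.004 without the filter; the cause was not tested. Of the list medians outside the random range, recomputed under each setting, 204 were close to the main value, 41 moved and 1 reversed. Against random lists drawn without matching, 1 of the 40 came back inside the range, the ribosomal proteins in the mating comparison. Genes past 2-fold kept that difference in 405 recomputed values and fell under it in 24, and none reversed.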

Other observations

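The families below were chosen after their values were seen. Lysozyme genes, whose products digest bacteria in the gut, followed the digestive genes at the sperm step. Over 6 genes the median was -0.60 in wild-type against virgin females, -0.40 after DTA-E males, 0.63 with Acps and -0.83 with sperm. LysC (-1.03), LysD (-0.91), LysE (-0.84) and LysB (-0.82) were lower with sperm, whereas LysS was higher by 0.10. These near-identical genes can share probes, so their values need not be independent. Bomanin genes encode short secreted peptides of the Toll response. The set of 9 genes taken for them also held Bbd, which does not carry the bomanin name. The median of the set was 0.62 with Acps and -0.07 with sperm, unlike Mtk, which was higher at both steps. BomBc3 (0.84), Bbd (0.80) and BomBc2 (0.79) were higher after spermless than after DTA-E males, and BomS6 was close to 0 at 0.03. Against virgin females the median of the 9 genes, Bbd included, was 0.31 after spermless males and -0.29 after DTA-E males.

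Metallothionein genes, which bind heavy metals, were highest after DTA-E males. MtnB differed by 0.66, MtnC by 0.55 and MtnA by 0.38 from virgin females, with a median of 0.55, and by -0.25, -0.51 and -0.24 between spermless and DTA-E males. Among kept probe sets without a single gene name, 8 were at least 2-fold higher after wild-type than after DTA-E males, 6 of the 811 were so after spermless males, and the highest difference was 2.10.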
